A study of Homo sapiens with 32 samples.

How the data were processed

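Poly(A)-selected, strand-specific RNA sequencing libraries of HEK293T cells were used, 32 in all, and each library was a separate sample. Per the labels' protocols, STM2457 was given at 20 µM in 0.2% DMSO (v/v) and the controls received 0.2% DMSO alone, siRNA was transfected at 20 nM 24 h after seeding, and cells were harvested 48 h after transfection, with STM2457 or DMSO added 42 h after transfection. Emetine, at 1.8 µM, was present for the last 2 h of the 6 h treatment. The deposited values are raw read counts per Ensembl gene ID, without normalization. Per the submitters' processing notes, the tools were FastQC 0.11.8, cutadapt 1.18 and 4.0, Trimmomatic, STAR 2.7.3a, SAMtools 1.9, Subread 2.0.0 and featureCounts, on genome build GRCh38.p12. The annotation release and the strand setting of the counting are not given in the sources used here, so reads from genes that overlap cannot be assigned with certainty. Besides the pairs given in the text, this holds for the named genes DEPP1 (RASSF4), IMP3 (SNX33), ZNF416 (ZIK1), DNAJB1 (TECR), SPSB2 (LRRC23, TPI1), PTRH2 (CLTC, VMP1), NPY1R (NPY5R), CRYBG3 (RIOX2), TAF11 (BLTP3A), CD302 (MARCHF7) and RAB5IF (SLA2). HNRNPL, INTS5, UQCR11, DYNLT3, ANKRD34A and ZNRF2 each overlap a protein coding gene without a symbol, so the same holds for them. For HNRNPL, INTS5 and UQCR11 that gene lies on the same strand.

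Each library held 60662 gene IDs, of which 60306 had a symbol and 58587 were in GENCODE release 29. In 24 libraries, those of the knockdown and emetine experiments, the tables also held counts of 92 ERCC spike-in RNAs, which were kept apart from the genes. Groups came from the labels alone. The labels call the libraries without YTHDF2 siRNA WT and do not say whether these received the control siRNA that the protocol mentions, so effects of transfection are not separated from those of YTHDF2 siRNA. Nothing in the labels says that replicates were separate cultures or that equal replicate numbers belong together, so the p-values measure only the spread between these samples.

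Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalization, the filterByExpr filter on the group factor and quasi-likelihood F tests, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The knockdown, 9 h and emetine experiments were fitted apart. In the differences between experiments, 1 fit held the 20 libraries without YTHDF2 siRNA or emetine. In this way 11 comparisons were made: 7 between groups (STM2457 in 5 settings, YTHDF2 siRNA, and emetine) and 4 of the difference between STM2457 effects. Positive log2 changes stand for higher levels in the treated group. Group levels are given in CPM, counts scaled to the library size after TMM, as mean ± SD over libraries, and fitted log2 changes with their standard error (SE).

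The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. In each comparison of groups the text names METTL3 and YTHDF2, the 8 protein coding genes with the largest positive and the 8 with the largest negative log2 change among those past the threshold, with a mean log2 CPM of at least 2 and no overlap between the libraries compared, and up to 4 members of each described list, by smallest p. For a difference between effects the largest 5 in each direction are named. The results of 3 genes that this rule would name are not reported here, so that some of these lists are shorter than the rule gives. Chromosomal positions are on GRCh38.

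Lists of genes, 30 in number, covered m6A writers, m6A readers and erasers, CCR4-NOT deadenylation, decapping and P bodies, factors and substrates of nonsense-mediated decay, immediate early genes, NF-kB response, integrated stress response, unfolded protein response, heat shock, p53 targets, interferon response, cholesterol synthesis, hypoxia and glycolysis, methionine and polyamine metabolism, G1/S and G2/M genes, mRNAs described as m6A-modified, genes of mitochondrial DNA, WNT targets, ribosomal proteins, zinc finger (ZNF) genes, HOX genes, replication histones, nuclear oxidative phosphorylation genes, and markers of fibroblasts, keratin epithelium, blood and hepatocytes. Each list was tested against the other genes with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over all 286 list tests, and again with an estimated correlation between genes. Lists with fewer than 5 measured members got values and no test. Of the 286 tests, 101 passed at the preset correlation and 17 of these also with an estimated correlation.

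The genes raised or lowered at 9 h formed a pair of gene sets that were followed in the other experiments, which share no library with the 9 h experiment. They were tested with camera, and per library by an exact two-sided permutation test on the set median, in which 3 libraries against 3 cannot give a p below 0.1. Sequence features came from the longest coding transcript per gene in GENCODE 29 for 19488 protein coding genes, and 29 genes were left out because annotation and sequence lengths differed. Motif slopes were regressions across genes of the log2 change on the logarithm of the number of DRACH motifs at least 100 nt from an exon junction, with lengths, GC content and expression as further terms. DRACH is a sequence motif (D: not C, R: purine, H: not G), and its occurrences are not measured m6A sites. The shuffled motif DRCAH and DRACH within 100 nt of a junction served as controls. All 16384 7-mers were compared between 3′UTRs of changed and unchanged genes of like length, in 5 searches.

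Alternatives covered size factors of the DESeq2 kind, scaling to ribosomal protein genes, no low-count filter, a stricter filter at mean log2 CPM 3, a replicate block, DESeq2 1.42.0 in place of edgeR, a fit of only the compared groups, each library left out in turn, other definitions of the gene sets and other motif settings. Scaling to the spike-ins, leaving out genes with a 7-mer site, leaving YTHDF2 out of the list of readers and erasers, fitting both motifs together, and picking a 7-mer on the genes of odd-numbered chromosomes to grade it on the others, and the reverse, were chosen after seeing the data. The pipeline was tested on simulated data, in which 92.0% of 50 genes given a 2-fold change were recovered for STM2457 at 6 h, 98.0% of 49 at 9 h and 70.0% of 50 for a difference between effects in the knockdown experiment. Unchanged genes made up 3.25% to 7.65% of the calls over the comparisons simulated. Far fewer genes were changed there than were called in the data (for STM2457 at 6 h, 170 calls among 16371 genes against 7491), so these shares do not carry over directly. Replicates of 1 group differed by more than counting error in each of 36 pairs, with a chi-square per degree of freedom of 1.89 to 38.3, so no library is a copy of another. The other kinds of data from the study were not analysed here.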

Results

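HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, were sequenced as poly(A) RNA in 32 libraries from 3 experiments. STM2457 inhibits METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) in mRNA. YTHDF2 is an m6A reader that brings mRNAs to the CCR4-NOT deadenylase, and emetine stops the elongation step of translation. The knockdown experiment (12 libraries) held 4 groups of 3, namely DMSO 6 h, STM2457 6 h, and each of these with YTHDF2 siRNA. The 9 h experiment (8 libraries) held 4 libraries with DMSO and 4 with STM2457. The emetine experiment (12 libraries) held 4 groups of 3, DMSO or STM2457 for 6 h with emetine or DMSO in the last 2 h. Gene counts per library came to 37694945 to 42303951 in the knockdown experiment, 22510323 to 34677704 at 9 h and 21781514 to 28053353 in the emetine experiment. The questions were which mRNAs rise or fall when m6A is depleted, and how much of that change is left when YTHDF2 is low or translation is stopped.

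YTHDF2 mRNA was lowered by its siRNA and raised by STM2457. YTHDF2 (ENSG00000198492.16, chromosome 1, 28736621 to 28769775) stood at 178 ± 3.91 CPM in DMSO, 618 ± 36.8 with STM2457, 43.3 ± 1.14 with YTHDF2 siRNA and 76.9 ± 3.28 with both (SD, n = 3 each). The log2 change with siRNA was −2.04 (SE 0.06, edgeR adjusted p = 8.25e-15). At 9 h YTHDF2 went from 196 ± 5.36 to 537 ± 22.1 CPM (SD, n = 4). In the emetine experiment it went from 231 ± 7.19 to 766 ± 7.57 CPM without emetine and from 328 ± 6.31 to 586 ± 3.81 with it (SD, n = 3), and emetine alone raised it by 0.50 (edgeR adjusted p = 5.12e-15). METTL3 (ENSG00000165819.12, chromosome 14, 21498133 to 21511375, overlapping TOX4) stood at 68.9 ± 0.292 CPM in DMSO, 75.6 ± 2.30 with STM2457, 58.2 ± 1.05 with YTHDF2 siRNA and 62.3 ± 0.831 with both. Its log2 change with STM2457 was 0.13 at 6 h (SE 0.04, edgeR adjusted p = 0.0197), which turned to −0.13 with scaling to ribosomal protein genes and −0.23 with scaling to spike-ins. At 9 h it was 0.03 (edgeR adjusted p = 0.512). In the emetine experiment METTL3 went from 61.5 ± 3.37 to 71.4 ± 3.87 CPM with STM2457 (log2 change 0.22, edgeR adjusted p = 0.000105), a call that ended with ribosomal protein and spike-in scaling, and to 68.3 ± 1.15 CPM with emetine alone (0.15, edgeR adjusted p = 0.00315). The rise with emetine alone grew to 0.59 and 0.64 with those scalings, and its call ended when DMSO replicate 1 or 2 was left out. With YTHDF2 siRNA METTL3 fell by 0.24 (edgeR adjusted p = 0.000112).

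**Figure D1:**
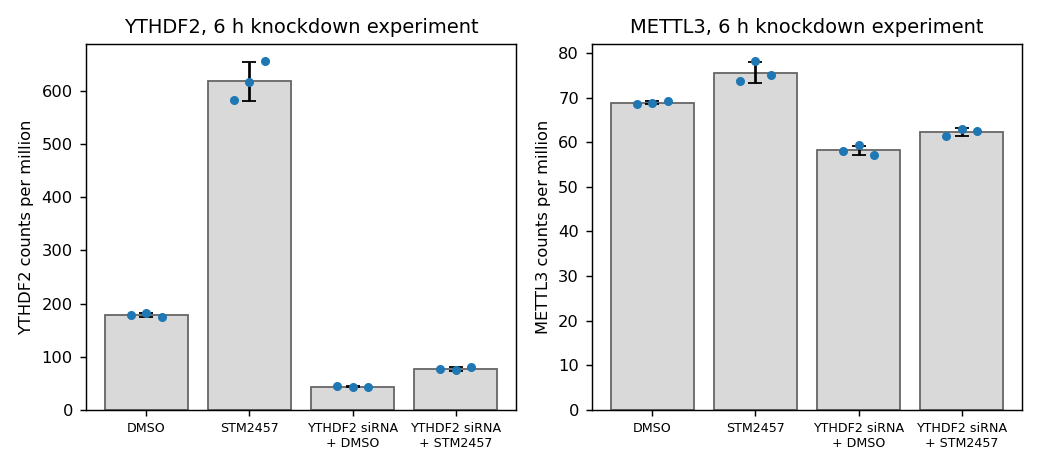
CPM of YTHDF2 (left) and METTL3 (right) in the 4 groups of the knockdown experiment, with bars for the mean, points for the 3 libraries and error bars for the SD. YTHDF2 reaches 618 CPM with STM2457 and 43.3 with its siRNA, while METTL3 lies between 58.2 and 75.6, and the sign of its difference between STM2457 and DMSO turns with ribosomal protein or spike-in scaling.

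STM2457 for 6 h in the knockdown experiment raised m6A writer and HOX genes, and lowered genes such as SDHAF1 and HNRNPLL. RBM15, an RNA-binding subunit of the m6A writer complex, rose by 2.22 on the log2 scale (SE 0.05), from 39.4 ± 0.354 to 184 ± 7.63 CPM (SD, n = 3). The transcription factors HOXD13 and ZNF503 rose by 1.94, TRIM13, a ubiquitin ligase of the endoplasmic reticulum that overlaps KCNRG, by 1.93, and MAD2L1BP, which silences the mitotic checkpoint, by 1.86. ID3, an inhibitor of helix-loop-helix factors, rose by 1.80, YTHDF2 by 1.79 and TENT5B, of a family of noncanonical poly(A) polymerases, by 1.78. SDHAF1, an assembly factor of succinate dehydrogenase, went from 15.98 ± 0.678 to 2.73 ± 0.355 CPM (log2 change −2.55, SE 0.09). HNRNPLL, a splicing regulator, fell by 2.39 (SE 0.06). Next came ATXN7L3B (−1.99), C14orf132 (−1.93), WDR6 (−1.86), SMIM10 (−1.85), ZNF33B (−1.78) and CHML, a Rab escort protein (−1.74). Of the 16 genes TENT5B had the highest edgeR adjusted p, 1.71e-08. WDR6 overlaps DALRD3 and P4HTM, and CHML overlaps OPN3, so that their reads are not assigned with certainty.

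Over all genes, 3814 were higher and 3677 lower of 16662 tested at 6 h, 292 and 504 of them by 2-fold or more. All 8 m6A writers rose (8 adjusted over the list alone), with RBM15B at 1.24, WTAP at 0.98 and METTL14 at 0.56, and METTL3 among them with a sign that turned under ribosomal protein and spike-in scaling. Camera gave the writers an adjusted p of 1.13e-15, and adjusted p = 0.0152 with an estimated correlation. Of 37 HOX genes, which set body axis identity, 29 rose and 1 fell (29 and 2 adjusted over the list alone), with HOXC9 at 1.15 and HOXA5 at 0.81. Their camera adjusted p was 4.47e-12, and adjusted p = 0.028 with an estimated correlation.

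Another 7 lists passed camera at 6 h (adjusted p = 5.21e-06 to 0.0059), but not with an estimated correlation (adjusted p = 0.113 to 0.838). Among 12 m6A readers and erasers 5 rose and 1 fell (5 and 1 adjusted over the list alone), with YTHDF3 at 1.04, YTHDF1 at 0.85 and YTHDC1 at 0.60, but their median of 0.05 turned negative under ribosomal protein and spike-in scaling. Of 17 mRNAs described as m6A-modified 11 rose and 3 fell (12 and 3 adjusted over the list alone), with MYC at 1.12 and SOX4 at 0.91. Of 36 immediate early genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with RHOB at 1.40 and ID2 at 1.08, and their median of 0.19 also turned under both scalings. Of 23 G2/M genes 13 fell (13 adjusted over the list alone), with CDC20 at −0.53 and UBE2C at −0.51. Substrates of nonsense-mediated decay rose in 11 and fell in 2 of 16 (12 and 2 adjusted over the list alone), with SNHG16 at 0.59 and a median of 0.34 that became −0.04 with spike-in scaling. Ribosomal protein genes rose in 64 of 84 (69 adjusted over the list alone), with RPS12 at 0.51 and a median that turned negative under ribosomal protein and spike-in scaling. ZNF genes rose in 215 and fell in 55 of 423 (218 and 58 adjusted over the list alone), with ZNF703 at 1.48 and a median that turned negative under the same scalings. Scaling to ribosomal protein genes moved the median of all genes by −0.26 and the split to 1252 higher and 7363 lower. Scaling to spike-ins moved it by −0.37 and the split to 398 and 5023.

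After 9 h of STM2457, TENT5B and PCDH10 had risen most and HNRNPLL and SDHAF1 had fallen most among the named genes. TENT5B rose by 2.91 (SE 0.09), and PCDH10, a protocadherin, by 2.61 (SE 0.04), from 80.5 ± 2.54 to 490 ± 27.3 CPM (SD, n = 4). ERRFI1, a feedback inhibitor of the EGF receptor, rose by 2.12, KCTD12, an auxiliary subunit of GABA-B receptors, by 1.95, TRIM13 by 1.93, ID3 by 1.92, FAT4, an atypical cadherin, by 1.87 and RBM15 by 1.74. HNRNPLL fell by 2.43 (SE 0.06), followed by SDHAF1 (−1.82) and the splicing factor HNRNPL (−1.47), which went from 398 ± 9.61 to 144 ± 5.64 CPM. DNASE1, an endonuclease gene that overlaps TRAP1 (−1.45), ZNF33B (−1.33), ARMH4, which overlaps ACTR10 and PSMA3 (−1.28), C14orf132 (−1.28) and SMIM14 (−1.22) came next. SMIM14 had the highest edgeR adjusted p of these 16 genes, 1e-09. In all, 5104 genes were higher and 5140 lower of 15834 tested, 393 and 168 of them by 2-fold or more.

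HOX genes rose in 34 and fell in 1 of 37 at 9 h (34 and 1 adjusted over the list alone), with HOXB9 at 1.23, HOXA11 at 1.19 and HOXA10 at 0.93. By camera their adjusted p was 9.19e-20, and adjusted p = 0.0464 with an estimated correlation. Of 8 writers 7 rose (7 adjusted over the list alone), RBM15B by 1.23, WTAP by 0.63 and CBLL1 by 0.56 (camera adjusted p = 1.03e-11, and adjusted p = 0.0363 with an estimated correlation). G2/M genes fell in 20 and rose in 2 of 22 (20 and 2 adjusted over the list alone), with CDC20 at −0.91, HMMR at −0.73 and the mitotic cyclin gene CCNB1 at −0.53. Camera gave them an adjusted p of 7.33e-09, and adjusted p = 0.0443 with an estimated correlation.

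At 9 h 7 more lists passed camera (adjusted p = 3.47e-09 to 0.00842) and lost the call with an estimated correlation (adjusted p = 0.138 to 0.663). G1/S genes fell in 15 and rose in 3 of 22 (15 and 3 adjusted over the list alone), with the replication helicase gene MCM7 at −0.57 and TYMS at −0.54. Nuclear oxidative phosphorylation genes fell in 60 and rose in 2 of 75 (61 and 2 adjusted over the list alone), with UQCR11 at −0.80 and ATP5PO at −0.63. Described m6A mRNAs rose in 14 of 17 (14 adjusted over the list alone), with SOX4 at 0.89 and CREBBP at 0.70. Immediate early genes rose in 21 of 34 (21 adjusted over the list alone), with RHOB at 1.14 and the phosphatase gene DUSP1 at 0.97. Readers and erasers rose in 7 and fell in 3 of 12 (7 and 3 adjusted over the list alone), and ZNF genes rose in 249 and fell in 49 of 417 (250 and 50 adjusted over the list alone). Ribosomal protein genes fell in 64 and rose in 1 of 85 (64 and 1 adjusted over the list alone), with a median of −0.16 that became 0.01 with scaling to these genes. That scaling moved the median of all genes by 0.17 and the split to 7513 higher and 2424 lower.

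In the emetine experiment STM2457 for 6 h without emetine raised RBM15, ID3, TENT5B and TRIM13 most and lowered SDHAF1 and HNRNPLL most among the named genes. RBM15 rose by 2.18 (SE 0.04), ID3 by 2.17, TENT5B by 2.06 and TRIM13 by 1.97. ADPRM (overlapping SCO1 and TMEM220) rose by 1.80, DEPP1 by 1.78, MED18, a subunit of the Mediator complex, by 1.76 and YTHDF2 by 1.73. SDHAF1 fell by 3.02 (SE 0.11), with HNRNPLL (−2.61), C14orf132 (−2.24), WDR6 (−2.17), ZNF33B (−2.15), KCTD11 (−2.14), SMIM10 (−1.94) and PCNX4, which overlaps DHRS7 (−1.92), next. KCTD11 had the highest edgeR adjusted p of these 16 genes, 1.7e-13. Of 15817 genes tested, 4108 were higher and 3459 lower, 291 and 456 of them by 2-fold or more. Scaling to ribosomal protein genes moved the median of all genes by −0.17 (2200 higher, 6688 lower) and scaling to spike-ins by −0.13 (2092 and 4679).

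All 8 writers rose in the emetine experiment as well (8 adjusted over the list alone; camera adjusted p = 3.48e-18, and adjusted p = 0.00321 with an estimated correlation). HOX genes rose in 26 and fell in 1 of 36 (28 and 1 adjusted over the list alone; camera adjusted p = 1.09e-11, and adjusted p = 0.0443 with an estimated correlation). Immediate early genes rose in 18 and fell in 1 of 35 (18 and 1 adjusted over the list alone), with RHOB at 1.29, MYC at 1.24 and ID2 at 1.15. Camera gave these an adjusted p of 4.04e-07, and adjusted p = 0.028 with an estimated correlation. A further 7 lists passed camera (adjusted p = 1.21e-06 to 0.0115) but not with an estimated correlation (adjusted p = 0.0791 to 0.866). Described m6A mRNAs rose in 11 of 17 (11 adjusted over the list alone), decay substrates rose in 14 and fell in 1 of 16 (14 and 1 adjusted over the list alone), and G2/M genes fell in 13 of 22 (14 adjusted over the list alone). Genes of the integrated stress response rose in 11 and fell in 2 of 21 (11 and 2 adjusted over the list alone), with CHAC1, an enzyme that degrades glutathione, at 1.04. Ribosomal protein genes rose in 69 and fell in 1 of 85 (72 and 1 adjusted over the list alone), and ZNF genes rose in 190 and fell in 52 of 416 (195 and 52 adjusted over the list alone). Readers and erasers rose in 6 and fell in 3 of 12 (6 and 4 adjusted over the list alone), with a median of 0.06 that turned negative under ribosomal protein and spike-in scaling.

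The 3 STM2457 experiments shared many genes. Of 15252 genes tested in all 3, 2483 were higher and 1697 lower in each, where 328 and 264 would come from independent calls. Between the knockdown and 9 h experiments 88.0% of 5612 genes called in both moved in the same direction, and between both 6 h experiments 99.5% of 5420. Across genes, Pearson's r of the knockdown experiment was 0.595 with the 9 h experiment and 0.817 with the emetine experiment, as a description, since genes are not independent replicates. Among genes with a mean log2 CPM of at least 3 it was 0.699 and 0.918.

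At 9 h the STM2457 effect differed from that at 6 h (knockdown experiment) in 6202 of 16720 genes, 2310 with a more positive and 3892 with a more negative effect at 9 h (edgeR interaction). CHML went from −1.74 at 6 h to 0.32 at 9 h (difference 2.03, SE 0.09), FAT4 from 0.20 to 1.87, DHFR2 (overlapping NSUN3) from −1.99 to −0.32, ATXN7L3B from −1.99 to −0.40, and NPY1R, a neuropeptide Y receptor, from −0.67 to 0.78. TMEM160 went from 0.23 to −0.98, RAB5IF (overlapping TGIF2-RAB5IF) from 0.73 to −0.31, C4orf48 from 0.36 to −0.62, SYBU from 0.42 to −0.46 and ADGRL3, a latrophilin, from 0.24 to −0.62. TMEM160 had the highest edgeR adjusted p of these differences, 0.000244. Ribosomal protein scaling moved the median difference of all genes by 0.47 and gave 10070 genes, 9973 of them more positive. Time and experiment cannot be told apart in this comparison.

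Between both 6 h experiments 141 genes differed, 40 more positive and 101 more negative in the emetine experiment. PIP5K1C, a phosphoinositide kinase, went from −0.02 in the knockdown experiment to 0.73 in the emetine experiment, NCEH1 from −0.29 to 0.42, ZNF608 from −0.21 to 0.40, ATP1B2 from −0.56 to 0.03 and SLC43A1 from −0.45 to 0.06. ZNRF2 went from −0.32 to −1.07, CRYBG3 from −0.76 to −1.41, UQCR11 from −0.57 to −1.20, ZNF780A from −0.40 to −0.99 and TAF11, a subunit of TFIID, from 0.47 to −0.08. ATP1B2 had the highest edgeR adjusted p of these, 0.0413. The count was 4 with ribosomal protein scaling, which moved the median of all genes by 0.13, and 369 with DESeq2, 288 without the low-count filter and 57 with a replicate block. It was 38, 79 and 38 without DMSO replicates 1, 2 and 3 of the knockdown experiment, 483 and 810 without its STM2457 replicates 1 and 2, 22 and 15 without DMSO replicates 1 and 2 of the emetine experiment, and 45, 25 and 24 without its STM2457 replicates 1, 2 and 3.

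The largest changes with YTHDF2 siRNA were falls. ENOX2 fell by 2.83 (SE 0.08), from 44.3 ± 1.56 to 6.21 ± 0.252 CPM (SD, n = 3). EPHA3, an ephrin receptor (−2.66), SCD5, a stearoyl-CoA desaturase (−2.62), SLC35F1 (−2.62), DYNLT3, a dynein light chain (−2.51), UMAD1, which overlaps RPA3 (−2.45), CCND1, which encodes cyclin D1 and overlaps LTO1 (−2.31), and CD302, which overlaps LY75-CD302 (−2.30), came next. ZNF585A (overlapping ZNF420) rose by 1.94 (SE 0.07), IGIP by 1.92, SOCS2, a suppressor of cytokine signalling, by 1.89, PRTG by 1.84, STING1, the adaptor of cytosolic DNA sensing, by 1.82, KLHL3 and ZNF530 by 1.80 and PSKH1 (overlapping CTRL) by 1.75. KLHL3 had the highest edgeR adjusted p of these 16 genes, 1.01e-08. In all, 5521 genes were higher and 4882 lower of 16662, 740 and 963 of them by 2-fold or more. Scaling to ribosomal protein genes gave 4607 higher and 3998 lower, and scaling to spike-ins 2653 and 2229.

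With YTHDF2 siRNA 6 lists passed camera (adjusted p = 3.72e-07 to 0.0386), each losing the call with an estimated correlation (adjusted p = 0.163 to 0.879). Among 12 readers and erasers 3 rose and 5 fell (3 and 5 adjusted over the list alone), YTHDF2, the target of the siRNA, among the 5, with YTHDF3, its paralog, at −1.14 and IGF2BP1 at −0.83. Without YTHDF2 this list was no longer called (median −0.09 over 11 genes, camera adjusted p = 0.256, adjusted p = 0.689 with an estimated correlation). Cholesterol synthesis genes fell in 13 and rose in 2 of 20 (13 and 3 adjusted over the list alone), with STARD4 at −0.86. Hypoxia and glycolysis genes fell in 10 and rose in 2 of 17 (10 and 2 adjusted over the list alone), with NDRG1 at −1.73 and ADM at −1.30. ZNF genes rose in 251 and fell in 58 of 423 (252 and 60 adjusted over the list alone), with ZNF211 at 1.64 but ZNF664 at −1.45. Oxidative phosphorylation genes fell in 44 and rose in 3 of 77 (44 and 3 adjusted over the list alone), with NDUFA1 at −1.18, and G2/M genes fell in 10 and rose in 4 of 23 (11 and 5 adjusted over the list alone), with the mitotic kinase gene AURKA at −1.16. The medians of these lists kept their sign under the other scalings, and ribosomal protein and spike-in scaling moved the median of all genes by 0.01 and 0.02.

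Part of the genes lowered by YTHDF2 siRNA held the sequence GCAAGCA in their 3′UTRs. It was found in 29.8% of 677 genes lowered by 2-fold or more and in 5.13% of 3997 genes that were not called (odds ratio 6.85). Its p, by a Cochran-Mantel-Haenszel test over classes of UTR length, was 8.46e-71 after Bonferroni correction for 16384 sequences. The same bases lie in the coding sequence of YTHDF2, in exon 4 (chromosome 1, 28742868 to 28742874), followed by A. Genes whose 3′UTR held the 8-base form GCAAGCAA had a median change, relative to genes of like UTR length, of −0.48 (311 genes). It was −0.27 with GCAAGCA (701), −0.11 with CAAGCAA (1090), 0.00 with CAAGCA (1717) and 0.04 with none of these (9100). These medians include the genes on which the sequence was found, and with it picked on some chromosomes and graded on the others the fall from no site to the 8-base form was 0.55 and 0.52. In that search 50 sequences passed Bonferroni correction, 22 with an odds ratio over 1.5. Among the 521 genes raised by 2-fold or more 102 passed, 73 with an odds ratio over 1.5, CTGCCCC first (32.1% against 18.9%, odds ratio 2.17). Genes with CTGCCCC had a median change 0.02 above that of genes with a rearrangement of its bases, where the difference for GCAAGCA was −0.37. In the other searches 2 sequences passed for genes lowered at 9 h, 1 for genes lowered by STM2457 in the knockdown and 0 for genes raised at 9 h. Of the 8 named genes with the largest falls 7 held a 7-base or 8-base site, SCD5 only as CAAGCAA, and of the 8 with the largest rises 1 did. The 8 with the largest falls are among the genes on which the sequence was found, so their count is no separate support. Of all 12919 genes searched, 311 held the 8-base form, 701 GCAAGCA and 1090 CAAGCAA as their longest.

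**Figure D2:**
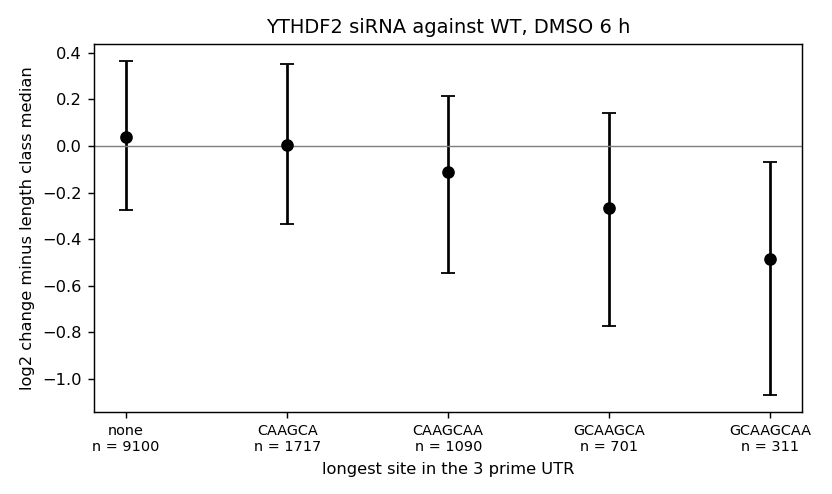
Log2 change with YTHDF2 siRNA minus the median of genes of like 3′UTR length, by the longest form of the sequence in the 3′UTR; points are medians over genes, bars reach from the lower to the upper quartile and n is the number of genes. The median falls from 0.04 without a site to −0.48 with the 8-base site.

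In cells with YTHDF2 siRNA, STM2457 for 6 h again raised ID3 and RBM15 and lowered SDHAF1 and CHML. ID3 rose by 2.02 (SE 0.09), RBM15 by 1.73, TENT5B by 1.66, TRIM13 by 1.44, GNB3, a G protein subunit gene that overlaps CDCA3, by 1.41, ADPRM and DEPP1 by 1.37, MAD2L1BP by 1.31 and YTHDF2 itself by 0.83. SDHAF1 fell by 2.45 (SE 0.09), followed by CHML (−2.21), ZNF33B (−2.10), WDR6 (−2.06), ATXN7L3B (−1.96), TSPYL4 (−1.88), CHMP6, a subunit of the ESCRT machinery (−1.82), and ZBTB26 (−1.76). GNB3 had the highest edgeR adjusted p of these genes, 8.57e-09. METTL3 changed by 0.10 (edgeR adjusted p = 0.109), which turned to −0.09 with ribosomal protein and −0.21 with spike-in scaling. In all, 2577 genes were higher and 2569 lower of 16662, 132 and 505 of them by 2-fold or more. Scaling to ribosomal protein genes moved the median of all genes by −0.19 (707 higher, 4245 lower) and scaling to spike-ins by −0.31 (138 and 2381).

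Of 8 writers 7 rose with STM2457 in the knockdown (8 adjusted over the list alone), with WTAP at 0.77 and RBM15B at 0.59 (camera adjusted p = 3.21e-15, and adjusted p = 0.0181 with an estimated correlation). Immediate early genes rose in 22 and fell in 1 of 36 (25 and 1 adjusted over the list alone), with MYC at 0.94 and ID2 at 0.91 (camera adjusted p = 3.3e-08, and adjusted p = 0.0443 with an estimated correlation). Another 9 lists passed camera (adjusted p = 9.96e-07 to 0.0476) but not with an estimated correlation (adjusted p = 0.0945 to 0.91). Described m6A mRNAs rose in 11 of 17 (11 adjusted over the list alone). HOX genes rose in 19 of 37 (20 adjusted over the list alone, with 1 lower), decay substrates in 14 of 16 (14 adjusted over the list alone) and ribosomal protein genes in 31 of 84 (48 adjusted over the list alone), each with a median that turned negative with spike-in scaling. CCR4-NOT genes rose in 8 and fell in 1 of 18 (9 and 2 adjusted over the list alone), with the antiproliferative partners BTG2 at 0.61 and BTG1 at 0.59 and a median that turned negative under ribosomal protein and spike-in scaling. Under the same scalings the medians turned of stress response genes, of which 9 rose and 1 fell of 21 (9 and 1 adjusted over the list alone), and of readers and erasers, of which 5 rose and 1 fell of 12 (5 and 1 adjusted over the list alone). They also turned for oxidative phosphorylation genes, of which 14 rose and 2 fell of 77 (3 and 2 adjusted over the list alone), and ZNF genes, of which 151 rose and 81 fell of 423 (163 and 84 adjusted over the list alone).

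Between cells with and without YTHDF2 siRNA the STM2457 effect differed in 1450 genes, 1154 more negative and 296 more positive in the knockdown (edgeR interaction). ALDH1B1, a mitochondrial aldehyde dehydrogenase, went from 0.99 without to −0.11 with YTHDF2 siRNA (difference −1.10, SE 0.07), ANKRD34A from 1.00 to −0.07, IMP3 from 0.56 to −0.48, KBTBD7 from 1.42 to 0.38 and INTS5, an Integrator subunit, from 1.08 to 0.05. PCDHGC3 (overlapping 21 other protocadherin genes) went from −1.66 to −0.78, BCHE, the butyrylcholinesterase, from −1.71 to −0.87, ARC from 0.26 to 1.05, ANTXR2 from 0.06 to 0.76 and ARMH4 from −1.67 to −0.99. ARC had the highest edgeR adjusted p of these, 0.0346. The count was 136 with ribosomal protein scaling and 0 by edgeR with spike-in scaling. In the latter fit 395 genes had an unadjusted p under the same threshold, fewer than that threshold gives when no gene differs. DESeq2 with its own size factors, and so without the spike-ins, called 1608. With TMM the edgeR count was 966 without DMSO replicate 1, 2196 without STM2457 replicate 3, 879 without replicate 1 of siRNA with DMSO and 928 without replicate 3 of siRNA with STM2457.

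Emetine for 2 h raised early response genes such as JUN and lowered chaperone genes such as HSPA1B and HSPA8. JUN, an AP-1 transcription factor, rose by 3.29 (SE 0.04), from 189 ± 3.95 to 1845 ± 68.1 CPM (SD, n = 3). TYW1B, whose reads are not separated with certainty from its paralog TYW1, rose by 3.29, TXNIP, an inhibitor of thioredoxin, by 2.92 and ARRDC3, of the arrestin family, by 2.72. MAP3K14, the NF-kB inducing kinase, went from 6.75 ± 0.419 to 43.9 ± 0.499 CPM, and ZNF416 rose by 2.53, the histone gene H2AC6 by 2.45 and ZNF256 by 2.41. TNFRSF10D, a decoy receptor for TRAIL, fell by 3.53 (SE 0.12). The chaperone genes HSPA1B (−3.40), HSPA8 (−2.89) and HSPA1A (−2.49), paralogs whose reads are not separated with certainty, were lower, as were CHAC1 (−2.75), ZC3HAV1, an antiviral RNA-binding protein (−1.85), and ZMAT3, a p53 target (−1.81). HSPA1A had the highest edgeR adjusted p of these genes, 6.84e-13. In all, 5360 genes were higher and 4477 lower of 15817, 978 and 125 of them by 2-fold or more. Scaling to ribosomal protein genes moved the median of all genes by 0.44 (11455 higher, 408 lower) and scaling to spike-ins by 0.49 (11558 and 227). With emetine the spike-ins' share of counts was 0.775 of that without (exact two-sided permutation p = 0.1, the smallest possible at 3 against 3).

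Heat shock genes fell in 12 of 13 with emetine (12 adjusted over the list alone), with DNAJB1 at −1.79 (camera adjusted p = 1.29e-20, and adjusted p = 0.028 with an estimated correlation). Immediate early genes rose in 17 and fell in 6 of 35 (17 and 6 adjusted over the list alone), with DUSP1 at 2.36, ATF3 at 2.17 and JUND at 1.62 (camera adjusted p = 2.27e-10, and adjusted p = 0.0121 with an estimated correlation). ZNF genes rose in 359 and fell in 12 of 416 (364 and 13 adjusted over the list alone), with ZNF16 at 2.33 and a median of 0.93 (camera adjusted p = 2.92e-41, and adjusted p = 0.00321 with an estimated correlation). For 8 further lists camera gave adjusted p = 4.57e-24 to 0.00114, and adjusted p = 0.0582 to 0.317 with an estimated correlation. Decay substrates rose in 11 and fell in 4 of 16 (11 and 4 adjusted over the list alone), with SNHG15 at 1.80 and SNHG1 at 1.75. Described m6A mRNAs rose in 12 and fell in 3 of 17 (12 and 3 adjusted over the list alone), and replication histone genes rose in 19 of 28 (19 adjusted over the list alone), with H4C14 at 4.81. Ribosomal protein genes fell in 82 and rose in 1 of 85 (82 and 1 adjusted over the list alone), with a median of −0.45 that became 0.03 with spike-in scaling. Unfolded protein response genes fell in 14 of 15 (14 adjusted over the list alone), with HERPUD1 at −1.40 and a median of −0.46 that became 0.02 with spike-in scaling. Cholesterol synthesis genes fell in 17 and rose in 1 of 20 (17 and 1 adjusted over the list alone), with INSIG1 at −1.55 and a median that turned positive under ribosomal protein and spike-in scaling. The same scalings turned the medians of oxidative phosphorylation genes, of which 70 fell and 1 rose of 75 (70 and 1 adjusted over the list alone), and of G2/M genes, of which 18 fell and 1 rose of 22 (18 and 1 adjusted over the list alone).

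With emetine present, STM2457 raised CHAC1 and HSPA1A, stress genes that emetine alone lowered, and again lowered ZNF33B, SDHAF1 and WDR6. CHAC1 rose by 2.94 (SE 0.15), from 0.976 ± 0.162 to 7.48 ± 0.455 CPM (SD, n = 3). KCNJ14, a potassium channel gene that overlaps GRWD1, rose by 2.28, GNB3 by 1.97, RBM15 by 1.81, HSPA1A by 1.53, MFSD5 by 1.43, FEM1C, a substrate receptor of a ubiquitin ligase, by 1.40, BAMBI, a decoy receptor of TGF-beta signalling, by 1.37 and YTHDF2 by 0.84. ZNF33B fell by 2.54 (SE 0.08), followed by SDHAF1 (−2.37), WDR6 (−2.06), SMIM10 (−2.02), ZBTB26 (−1.97), TSPYL4 (−1.96), DHFR2 (−1.95) and KCTD11 (−1.89). HSPA1A had the highest edgeR adjusted p of these genes, 1.35e-06. METTL3 changed by 0.08 (edgeR adjusted p = 0.133), which became −0.02 with ribosomal protein scaling and −0.000745 with spike-in scaling. In all, 3409 genes were higher and 2563 lower of 15817, 111 and 502 of them by 2-fold or more. Scaling to ribosomal protein genes moved the median of all genes by −0.11 (1660 higher, 4364 lower), and scaling to spike-ins changed the split to 1351 and 2581.

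Of 8 writers 6 rose with STM2457 in emetine (6 adjusted over the list alone; camera adjusted p = 1.69e-17, and adjusted p = 0.00321 with an estimated correlation). Immediate early genes rose in 18 and fell in 2 of 35 (18 and 3 adjusted over the list alone), with MYC at 1.12 and RHOB at 0.88 (camera adjusted p = 1.73e-06, and adjusted p = 0.028 with an estimated correlation). A further 9 lists passed camera (adjusted p = 5.21e-06 to 0.0218) but not with an estimated correlation (adjusted p = 0.247 to 0.879). Stress response genes rose in 11 of 21 (11 adjusted over the list alone), with DDIT4 at 0.93 and SESN2 at 0.69, and readers and erasers rose in 8 of 12 (8 adjusted over the list alone). Heat shock genes rose in 5 of 13 (5 adjusted over the list alone), with DNAJB1 at 1.24 and HSPA1B at 1.17, but their median of 0.06 turned negative under ribosomal protein and spike-in scaling. HOX genes rose in 21 and fell in 4 of 36 (23 and 4 adjusted over the list alone), with HOXD13 at 0.91 and HOXA6 at −0.77. Decay substrates rose in 13 and fell in 1 of 16 (13 and 1 adjusted over the list alone), and described m6A mRNAs rose in 11 and fell in 3 of 17 (11 and 3 adjusted over the list alone). CCR4-NOT genes rose in 9 and fell in 1 of 18 (10 and 1 adjusted over the list alone), and ribosomal protein genes rose in 57 of 85 (61 adjusted over the list alone). Replication histone genes fell in 12 and rose in 1 of 28 (13 and 1 adjusted over the list alone), with H2AC11 at −1.81.

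Between cells with and without emetine the STM2457 effect differed in 2810 genes, 1748 more negative and 1062 more positive in emetine (edgeR interaction). HNRNPLL went from −2.61 without to −0.74 with emetine (difference 1.86, SE 0.10), CHAC1 from 1.04 to 2.94, KCNJ14 from 0.99 to 2.28, DNAJB1 from 0.29 to 1.24 and AOC2 from −0.85 to 0.05. ID3 went from 2.17 to 0.66 (difference −1.51, SE 0.06), ADPRM from 1.80 to 0.51, SPSB2 from 1.25 to −0.03, PTRH2, a mitochondrial peptidyl-tRNA hydrolase, from 1.14 to −0.03 and HOXA6 (overlapping HOXA3) from 0.38 to −0.77. AOC2 had the highest edgeR adjusted p of these, 0.0012. With ribosomal protein scaling 1343 genes were more positive and 936 more negative, and with spike-in scaling 227 and 478.

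The genes raised at 9 h rose less with STM2457 in cells with YTHDF2 siRNA, which also lowered YTHDF3, or when emetine was present. Of these 5104 genes 5061 were tested in the knockdown experiment and 5024 in the emetine experiment. Their median change was 0.258 ± 0.0374 without and 0.127 ± 0.00912 with YTHDF2 siRNA, and 0.303 ± 0.000287 without and 0.157 ± 0.00856 with emetine (mean ± SD over 3 libraries). Each value is an STM2457 library against the mean of its control group, so these SDs leave out the spread of the controls. In each pair the exact two-sided permutation p was 0.1, the smallest possible, and 49.1 ± 7.94% and 51.9 ± 2.83% of the change was left, again without the spread of the controls. With that spread included, the difference averaged over libraries was −0.131 ± 0.0422 in the knockdown and −0.147 ± 0.0229 with emetine (SD, n = 3 per group). The fitted difference was −0.14 in the knockdown (camera adjusted p = 7.75e-21, and adjusted p = 0.0019 with an estimated correlation) and −0.15 with emetine (camera adjusted p = 6.91e-28, and adjusted p = 0.000192 with an estimated correlation). Of the 5140 genes lowered at 9 h, 5114 and 5098 were tested, with medians of −0.137 ± 0.0212 without and −0.0466 ± 0.0152 with YTHDF2 siRNA, and of −0.130 ± 0.00412 without and −0.0301 ± 0.0128 with emetine. Under ribosomal protein and spike-in scaling the median of the raised set became −0.01 and −0.11 without siRNA and −0.07 and −0.19 with it, and the fitted difference −0.07 and −0.09. In the emetine experiment it became 0.12 and 0.16 without emetine and 0.05 and 0.07 with it, and the fitted difference −0.09 and −0.10. Averaged over libraries, 38.2% and 43.2% of the change was then left with emetine. Relative to the other genes the raised set stood 0.31 higher without and 0.16 higher with YTHDF2 siRNA, which a scaling of whole libraries leaves nearly as it is by construction. With YTHDF2 siRNA alone the raised set stood at 0.15 (camera adjusted p = 0.000821, adjusted p = 0.11 with an estimated correlation) and the lowered set at −0.08 (camera adjusted p = 0.000536, adjusted p = 0.130 with an estimated correlation).

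**Figure D3:**
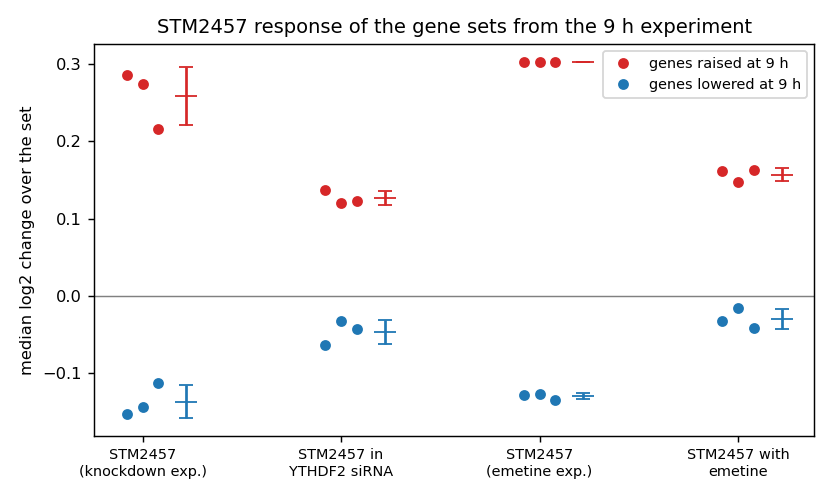
Median log2 change over the genes raised (red) and lowered (blue) at 9 h, for each STM2457 library against the mean of its control group in 4 comparisons; points are libraries, and the lines beside them give mean and SD (n = 3). The raised set lies lower with YTHDF2 siRNA (0.127) and with emetine (0.157) than without (0.258 and 0.303), and with ribosomal protein or spike-in scaling its median turns negative in the knockdown experiment and falls to 0.12 or 0.16 without and 0.05 or 0.07 with emetine.

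The change with STM2457 rose with the number of DRACH motifs in the coding sequence (CDS) at least 100 nt from an exon junction. Across protein coding genes (13410 in the knockdown experiment, 13096 at 9 h and 13142 in the emetine experiment) the slope per doubling of the count was 0.0890 ± 0.00227 at 6 h (SD over 3 libraries), and it was 0.115 ± 0.00247 at 9 h (4 libraries) and 0.0867 ± 0.00167 in the emetine experiment. With YTHDF2 siRNA it was 0.0339 ± 0.000675 and with emetine 0.0222 ± 0.00278. Slopes were taken per treated library, so these SDs and the permutation test on the slopes leave out the spread of the controls. The difference was −0.0551 with YTHDF2 siRNA and −0.0645 with emetine (exact two-sided permutation p = 0.1 each, the smallest possible). In 3′UTRs the slope was −0.0024 ± 0.0193 at 6 h, 0.0527 ± 0.00511 at 9 h, 0.0095 ± 0.00459 in the emetine experiment, −0.0155 ± 0.0023 with YTHDF2 siRNA and −0.003 ± 0.00677 with emetine. In 5′UTRs it lay between −0.0113 at 6 h and 0.0034 at 9 h in the same comparisons. The CDS slope was not specific to DRACH, since the shuffled motif DRCAH gave 0.0888 at 6 h, 0.114 at 9 h, 0.0338 with YTHDF2 siRNA and 0.0238 with emetine. In a joint regression at 6 h DRACH kept 0.0520 and DRCAH 0.0425, and DRACH kept 0.0673 at 9 h, 0.0513 in the emetine experiment, 0.0195 with YTHDF2 siRNA and 0.00599 with emetine. DRACH motifs within 100 nt of a junction gave −0.0982 at 6 h and −0.137 at 9 h. YTHDF2 siRNA alone gave 0.0381 and emetine alone 0.0578.

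**Figure D4:**
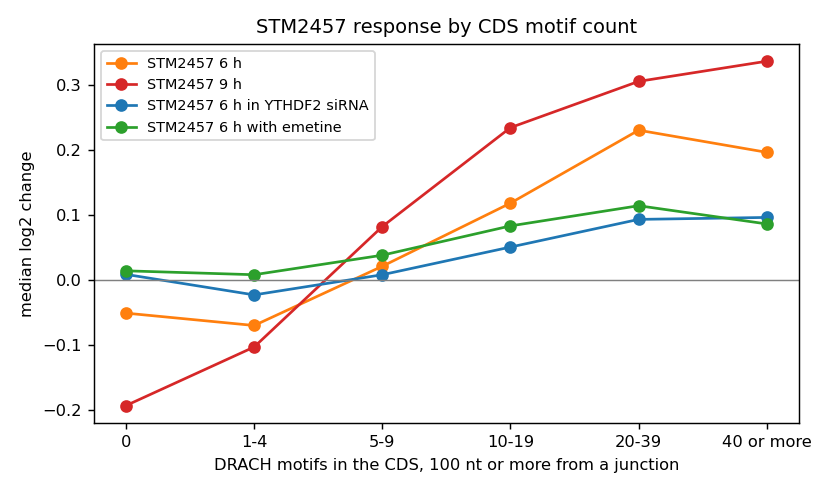
Median log2 change (vertical axis) of genes in 6 bins of the number of CDS DRACH motifs at least 100 nt from a junction (horizontal axis), with a line each for STM2457 at 6 h, at 9 h, at 6 h in YTHDF2 siRNA and at 6 h with emetine. From genes without a motif to genes with 40 or more, the median goes from −0.19 to 0.34 at 9 h, from −0.05 to 0.20 at 6 h, from 0.01 to 0.10 in YTHDF2 siRNA and from 0.01 to 0.09 with emetine, while a change of scaling moves all points of a line together.

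By camera X-linked genes stood apart from autosomal genes in 1 comparison. With emetine the median of 452 X-linked genes differed from that of autosomal genes by −0.12 (camera adjusted p = 0.0170, adjusted p = 0.114 with an estimated correlation). In the other comparisons tested the camera adjusted p was 0.301 to 0.682. Against 10000 random lists of autosomal genes of like expression, drawn as if genes were independent, the X-linked median lay at percentile 0 with STM2457 at 6 h (difference −0.05) and 9 h (−0.08) and with emetine, 0.01 with YTHDF2 siRNA (−0.11) and 0.18 with STM2457 in the emetine experiment (−0.04). It lay at percentile 0.78 with STM2457 in the knockdown and 0.92 with STM2457 in emetine (−0.02 each).

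Of the 30 lists 11 were called in none of the 11 comparisons. Over the comparisons between groups, median changes ran from −0.18 at 9 h to 0.34 with emetine for NF-kB response genes (up to 13 tested). They ran from −0.02 to 0.19 for 14 factors of nonsense-mediated decay and from −0.12 to 0.13 for 10 WNT targets. Medians were 0.02 to 0.28 for interferon response genes (up to 18 tested) and −0.09 to 0.04 for 16 genes of methionine and polyamine metabolism. For the 13 protein coding genes of mitochondrial DNA they were −0.12 to 0.19, and for 16 p53 targets 0.03 to 0.20. Markers of other cell types were too few for a test. At most 4 fibroblast genes (medians −0.58 to 0.17) and 3 keratin epithelium genes (−0.28 to 0.38) passed the count filter of edgeR. At most 3 blood genes (−0.46 to 0.46) and 0 hepatocyte genes passed it.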

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

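The difference of the raised set by itself under other scalings, the loss common to all responding genes or to the protein coding ones, the raised set without site genes, the comparison of both 6 h experiments as a measure of 9 h against 6 h, both gradings of 3′UTR sites by length, the spike-in scaling and the counts without site genes were tests chosen after the result was seen.

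YTHDF2 siRNA lowered 963 genes by 2-fold or more, and of all 7-mers GCAAGCA was the most enriched in the 3′UTRs of those searched, with an odds ratio of 6.85. It lies in the YTHDF2 transcript. A trend on GC content, length and expression accounted for the larger part of the fall in 0.142% of 702 protein coding genes lowered 2-fold or more. The trend held 7.87% of the variance, and the log2 change had a Spearman correlation of 0.250 with GC content. The share was at most 0.182% in every comparison checked, for rises and falls alike, so it does not set this comparison apart. The fitted trend was thus not the larger part of these falls, and whether it added a smaller part is not decided. Silencing of other mRNAs through the seed of the siRNA is a candidate explanation for part of the falls, since the same sequence was found with the genes of odd-numbered chromosomes or with the others alone, and in the part not used to find it the medians fell in order of site length, by 0.554 and 0.522 from no site to the 8-base site. Genes that held it were there 0.342 and 0.390 below genes with a rearrangement of the same bases (differences of −0.342 and −0.390). Over all genes the fall was 0.52, which cannot speak for the sequence, as it was found on these genes, and the siRNA sequence is not in the labels. Of the lowered genes searched 315 hold no site, YTHDF3 holds only the 6-base form, and for these the loss of YTHDF2 itself stays open and untested. Effects of transfection are open for all falls, as the labels do not say whether the other libraries received a control siRNA.

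The raised set rose less with STM2457 when YTHDF2 was low or emetine was present (differences of −0.139 and −0.155), and the lowered set fell less (0.0639 and 0.0828). How far normalization accounts for the smaller rise is open. The raised set minus the other genes stood at −0.143 in the knockdown and −0.144 with emetine under 3 other scalings, but a scaling moves all genes alike, so this outcome was fixed. The difference of the raised set by itself, over libraries, came as near to 0 as −0.0529 ± 0.246 in the knockdown and −0.0814 ± 0.0909 with emetine, both with ribosomal protein scaling (SD, n = 3 per group), within its spread. In the knockdown the number of genes that differed fell from 1450 to 136 with ribosomal protein scaling and to 0 by edgeR with spike-in scaling. In the latter fit 395 had an unadjusted p under 0.05, fewer than that threshold gives when no gene differs. DESeq2 with its own size factors, and so without the spike-ins, called 1608. A loss of response common to all responding genes is argued against, since genes lowered 2-fold or more at 9 h kept 94.8 ± 5.78% of their change in the knockdown (155 genes) and 85.2 ± 8.54% with emetine (153 genes), against 49.1 ± 7.94% and 51.9 ± 2.83% for the raised set and 61.1 ± 7.69% and 53.7 ± 5.73% for genes raised 2-fold or more (gaps to the latter of 33.7 ± 9.62 and 31.5 ± 10.3 percentage points). The lowered set as a whole kept 34.0 ± 12.3% and 23.2 ± 9.88%. The SDs of these shares are over 3 STM2457 libraries per group and leave out the spread of the controls. Of the strongly lowered genes 38.7% were protein coding, against 72.3% of the strongly raised. Genes that are not protein coding and were lowered 2-fold or more kept 96.2 ± 7.86% in the knockdown (92 genes) and 92.6 ± 6.14% with emetine (93 genes). Those raised 2-fold or more kept 62.8 ± 9.27% (95 genes) and 62.6 ± 17.6% (86 genes), so the gap was present within this class. Protein coding genes lowered 2-fold or more kept 79.9 ± 10.5% and 69.0 ± 16.7%, against 60.6 ± 8.25% and 53.4 ± 3.79% for those raised 2-fold or more (gaps of 19.4 ± 13.4 and 15.6 ± 17.1 points), so a loss common to protein coding genes stays open. A role of YTHDF2 or of translation in the rise is a hypothesis that stays open beside normalization, and so do indirect effects of the siRNA. YTHDF3 was low as well with YTHDF2 siRNA, at 50.5 against 111 CPM in DMSO and 68.3 against 229 CPM with STM2457. Loss of YTHDF2 and of YTHDF3 thus cannot be told apart here. In the knockdown the smaller rise was not confined to genes with a seed site. Without site genes the raised set still differed by −0.139 and 1142 of 14560 genes differed. Genes with the 8-base site had a median difference of −0.027 against 0.002 with none. This argues against sites in the genes themselves as the cause for genes without a site only. As most genes held no site, leaving site genes out could move the set median little, and silencing of other genes through the seed is not addressed.

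At 9 h the STM2457 effect differed from that at 6 h in 6202 genes. Correcting each library for its own trend on GC content and length left 5321 calls where 5851 stood before (90.9%), 4308 of them called both before and after. The Spearman correlation of the difference with GC content went from 0.299 to 0.102, so part of the GC trend remained. The calls left thus argue against only the removed part of the trend as the whole cause. Such a trend may account for part, as the median difference went from −0.51 to −0.28 for ribosomal protein genes and from −0.44 to −0.17 for oxidative phosphorylation genes. These medians also depend on scaling, that of oxidative phosphorylation genes turning with ribosomal protein scaling. The comparison of both 6 h experiments called 2.27% as many genes. With 1 library left out this share ran from 0.242% to 12.5%, the highest without STM2457 replicate 2 of the knockdown experiment, and it was 6.35% with DESeq2. This single pair shows nothing about other ways in which the 9 h experiment differed, so longer treatment and the experiment itself cannot be told apart.

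Other splits of the libraries were fitted with edgeR for each count of genes. At 9 h 1 of 35 splits, the real one, gave as many genes (10244, highest other 0), a share under 0.05 that argues against chance among these libraries. For groups of 3 against 3 the 10 splits are too few for a share under 0.05, and the real counts with the highest other were 7491 and 0 for STM2457 at 6 h, 10403 and 0 for YTHDF2 siRNA, 5146 and 0 for STM2457 in the knockdown, 7567 and 0 for STM2457 in the emetine experiment, 9837 and 0 for emetine, and 5972 and 0 for STM2457 with emetine. For the differences between effects 100 splits were drawn. In the knockdown 3 of them gave as many genes (1450, highest other 4586) and between 9 h and 6 h 2 did (6202, highest other 11255). These shares are under 0.05, but as some other splits gave more genes and not all possible splits were drawn, they do not by themselves exclude chance. With emetine 5 did (2810, highest other 4626) and between both 6 h experiments 7 did (141, highest other 6146), so chance is not excluded there by this share. The other splits with as many genes, namely 2, 1, 4 and 6 in the same order, relabelled the treatments unequally and thus carried the other factor, a structure of the samples. The splits drawn that relabelled the treatments equally, 44, 41, 44 and 44 in the same order, gave at most 0 genes.

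Differences between STM2457 effects were tested gene by gene with edgeR. In the knockdown against no knockdown they were 0.88 for PCDHGC3, 0.84 for BCHE, 0.79 for ARC, 0.70 for ANTXR2, 0.67 for ARMH4, −1.10 for ALDH1B1, −1.07 for ANKRD34A, −1.04 for IMP3 and −1.03 for KBTBD7 and INTS5. With emetine against without they were 1.89 for CHAC1, 1.86 for HNRNPLL, 1.29 for KCNJ14, 0.94 for DNAJB1, 0.89 for AOC2, −1.51 for ID3, −1.29 for ADPRM, −1.28 for SPSB2, −1.17 for PTRH2 and −1.15 for HOXA6. At 9 h against 6 h they were 2.03 for CHML, 1.64 for FAT4, 1.63 for DHFR2, 1.56 for ATXN7L3B, 1.42 for NPY1R, −1.25 for TMEM160, −1.08 for RAB5IF, −1.02 for C4orf48, −0.92 for SYBU and −0.90 for ADGRL3. Between both 6 h experiments they were 0.72 for PIP5K1C, 0.67 for NCEH1, 0.58 for ZNF608, 0.56 for ATP1B2, 0.48 for SLC43A1, −0.79 for ZNRF2, −0.69 for CRYBG3, −0.67 for UQCR11, −0.62 for ZNF780A and −0.59 for TAF11.

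Lists of genes also differed between STM2457 effects by camera. In the knockdown the median difference was −0.16 for HOX genes, −0.16 for ZNF genes, −0.13 for writers, 0.17 for G2/M genes, 0.14 for cholesterol synthesis genes, 0.14 for unfolded protein response genes, 0.0873 for stress response genes and 0.0011 for readers and erasers, whose mean was −0.13. The list of readers and erasers holds YTHDF2, the target of the siRNA, at −0.96, and was not tested without it for this difference. All these lists had camera adjusted p = 5.54e-07 to 0.0478, and adjusted p = 0.0807 to 0.781 with an estimated correlation. With emetine HOX genes had a median difference of −0.35 (camera adjusted p = 4.47e-12, and adjusted p = 0.0363 with an estimated correlation). Further medians there were −0.26 for described m6A mRNAs, −0.18 for writers, −0.17 for ZNF genes, −0.14 for decay substrates, −0.11 for immediate early genes, 0.13 for G2/M genes, 0.13 for heat shock genes, 0.0438 for cholesterol synthesis genes and −0.0114 for readers and erasers, the last turning with ribosomal protein and spike-in scaling. Their camera adjusted p = 3.14e-06 to 0.0286 became adjusted p = 0.0667 to 0.663 with an estimated correlation.

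At 9 h against 6 h the median difference was 0.16 for HOX genes and −0.51 for ribosomal protein genes. It was −0.44 for oxidative phosphorylation, −0.27 for heat shock, −0.24 for G1/S, −0.22 for G2/M, −0.20 for CCR4-NOT and −0.18 for decapping and P body genes, each turning positive with ribosomal protein scaling. Camera gave these lists adjusted p = 3.95e-26 to 0.0398, and adjusted p = 0.219 to 0.452 with an estimated correlation. Between both 6 h experiments stress response genes differed by 0.12 (camera adjusted p = 1.75e-06, and adjusted p = 0.0363 with an estimated correlation). The medians were 0.13 for unfolded protein response, 0.0714 for immediate early and −0.14 for heat shock genes, and −0.14 for ribosomal protein, −0.13 for oxidative phosphorylation and −0.0694 for ZNF genes, the latter 3 turning with ribosomal protein scaling. These had camera adjusted p = 2.97e-08 to 0.0474, and adjusted p = 0.411 to 0.71 with an estimated correlation.

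Single libraries stood apart from the other 3 of their group at 9 h in 12 of 115 values tested, by Dixon's test, where chance gives 5%. With DMSO, replicate 3 had ERRFI1 at 44.3 CPM (others 42.3 to 42.6), FAT4 at 14.7 (15.5 to 15.7) and TRIM13 at 25.1 (27.8 to 28.0), and replicate 2 had TYMS at 188.5 (182.3 to 183.2). With STM2457, replicate 1 had ID3 at 170.5 (214.6 to 217.9), RPL24 at 359.3 (413.5 to 425.2) and WTAP at 196.8 (213.04 to 216.2), and replicate 2 had METTL3 at 88.4 (91.3 to 91.5). Replicate 3 had ZNF33B at 17.03 (20.3 to 20.8), and replicate 4 had CCNB1 at 204.4 (206.8 to 207.1), HNRNPL at 152.5 (140.3 to 142.03) and RPL35A at 273.5 (259.6 to 260.3).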

How the results depend on the processing

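Scaling to spike-ins, leaving out genes with a 7-mer site, leaving YTHDF2 out of the list of readers and erasers and fitting both motifs together were tests chosen after seeing the data. Small changes were often missed in simulated data: of 1.2-fold changes 34.7% were recovered for STM2457 at 6 h, 62.0% at 9 h and 2.0% for the difference in the knockdown. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter, so these shares do not carry over directly. Whether equal replicate numbers pair the libraries was not settled. Correlations of residuals between equal numbers were mixed, from −0.35 to 0.58 in the knockdown experiment (8 of 18 over 0.1), from −0.13 to 0.31 in the emetine experiment (3 of 18) and from −0.10 to 0.09 at 9 h (0 of 4). Of 502 values of named genes, 502 kept direction and side of the threshold with size factors of the DESeq2 kind, 500 with DESeq2, 499 without the low-count filter, 495 with a replicate block and 417 with ribosomal protein scaling, as did 271 of 388 with spike-in scaling, 307 of 308 with only the compared groups and 3929 of 4044 without 1 library. Of 286 list tests 202 were the same with an estimated correlation and 84 were weaker. With fry 194 were the same, 7 weaker and 85 stronger, and with a replicate block 281 were the same. The call of readers and erasers with YTHDF2 siRNA ended without YTHDF2 (median −0.088). YTHDF2 fell by 2.02 to 2.09 with its siRNA under all alternatives run, and the number of genes changed ran from 5421 to 8615 for STM2457 at 6 h, 9363 to 10414 at 9 h, 6708 to 8888 in the emetine experiment and 8801 to 11863 for emetine. Apart from the estimated correlation, which widens the test by construction, the cause of the changes below was not tested.

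With an estimated correlation the call ended for the raised set (0.146) and the lowered set (−0.0821) under YTHDF2 siRNA and for X-linked genes with emetine (−0.116).

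With ribosomal protein scaling 136 genes differed in the knockdown, 10070 between 9 h and 6 h and 4 between both 6 h experiments. METTL3 turned to −0.13 with STM2457 at 6 h, −0.0911 in the knockdown and −0.0223 with emetine, and its difference to 0.0346 in the knockdown and 0.33 at 9 h against 6 h. YTHDF2 turned to 0.10 at 9 h against 6 h and 0.0284 between both 6 h experiments. Differences at 9 h against 6 h turned to 0.0718 for CNOT10, 0.10 for BTG1, 0.0496 for BTG3, 0.0243 for PCNA, 0.0833 for MCM7, 0.16 for MCM6, 0.0567 for CDC20, 0.0700 for CDK1, 0.19 for KIF20A, 0.0236 for LSM7, 0.0648 for LSM4, 0.0439 for DNAJA1, 0.0236 for HSP90AA1 and 0.0134 for NDUFS8. The raised set turned to −0.00625 with STM2457 at 6 h and −0.0655 in the knockdown, and the lowered set to 0.358 with emetine.

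With spike-in scaling 4882 genes changed with YTHDF2 siRNA, 2519 with STM2457 in the knockdown and 3932 with STM2457 in emetine, 705 differed with emetine and 0 in the knockdown (edgeR). For the difference in the knockdown 395 genes had an unadjusted p under 0.05, fewer than that threshold gives when no gene differs. DESeq2 with its own size factors, and so without the spike-ins, called 1608 there. METTL3 turned to −0.23 with STM2457 at 6 h, −0.21 in the knockdown and −0.000745 with emetine, and its difference in the knockdown to 0.0163. RPL21 turned to −0.00716 at 6 h. In the knockdown SNHG1 turned to −0.0262, DANCR to −0.0088, ZFP36L1 to −0.0242, ATP5F1E to −0.0478, RPL22 to −0.0771 and RPLP1 to −0.0297, and with emetine alone CCNB1 to 0.0384, UQCRH to 0.00774 and RPLP2 to 0.00148. The raised set turned to −0.112 at 6 h and −0.189 in the knockdown, and the lowered set to 0.408 with emetine.

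Between both 6 h experiments 288 genes differed without the low-count filter, 57 with a replicate block and 369 with DESeq2, and from 15 without replicate 2 of DMSO of the emetine experiment to 810 without replicate 2 of STM2457 of the knockdown experiment. Also far from 141 were 38, 79 and 38 without DMSO replicates 1, 2 and 3 and 483 without STM2457 replicate 1 of the knockdown experiment, 22 without DMSO replicate 1 and 45, 25 and 24 without STM2457 replicates 1, 2 and 3 of the emetine experiment. In the knockdown the number that differed ran from 879 without replicate 1 of siRNA with DMSO to 2196 without STM2457 replicate 3, with 966 without DMSO replicate 1 and 928 without replicate 3 of siRNA with STM2457. The METTL3 difference in the knockdown ran from −0.0468 without replicate 3 of siRNA with DMSO to 0.0023 without STM2457 replicate 2, and that between both 6 h experiments from −0.00286 without STM2457 replicate 3 to 0.0852 without DMSO replicate 3 of the emetine experiment. With genes called in both the 9 h and the other 6 h experiment the lowered set turned to 0.0232 with emetine.

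Among genes with a mean log2 CPM of at least 3, Pearson's r across genes, which are not independent replicates, went from 0.595 to 0.699 for STM2457 at 6 h with 9 h, 0.817 to 0.918 with the emetine experiment and 0.708 to 0.741 with STM2457 in emetine. It went from 0.130 to 0.219 for YTHDF2 siRNA with STM2457 at 9 h, 0.0694 to 0.125 with STM2457 of the emetine experiment, 0.0993 to 0.199 for emetine with STM2457 at 9 h and 0.00269 to 0.150 with STM2457 at 6 h.

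The CDS motif slopes at 200 nt from a junction, with GGACH, at mean log2 CPM of at least 3 and with both motifs together were in this order 0.0804, 0.121, 0.104 and 0.0520 for STM2457 at 6 h and 0.0987, 0.154, 0.121 and 0.0673 at 9 h. They were 0.0296, 0.0484, 0.0445 and 0.0195 in the knockdown, 0.0751, 0.119, 0.0978 and 0.0513 in the emetine experiment and 0.0192, 0.0387, 0.0327 and 0.00599 with emetine. YTHDF2 siRNA gave 0.0341, 0.0406, 0.0512 and 0.0460, and emetine 0.0522, 0.0435, 0.0550 and 0.0549. In the 3′UTR the slope turned to −0.0054 with GGACH in the emetine experiment, and for emetine to 0.00261 with GGACH and 0.00372 with both motifs.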

Other observations

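The gene classes and the spike-in shares below were described after seeing the data. Among the genes lowered by STM2457 were many long noncoding RNAs. At 6 h 275 of 2005 long noncoding genes were lower by 2-fold or more (13.7%), against 1.12% of 13456 protein coding genes. In the emetine experiment it was 250 of 1758 (14.2%) against 1.01%, with YTHDF2 siRNA 274 of 2005 (13.7%) against 1.07%, and with emetine 279 of 1758 (15.9%) against 1.05%. At 9 h 78 of 1781 long noncoding genes were lower by 2-fold or more (4.38%), against 0.495% of protein coding genes, but 81 were higher by 2-fold or more (4.55%), 410 were higher and 351 lower in all, and their median change was 0.03, where it had been −0.20 at 6 h. With emetine alone 20.9% of 626 pseudogenes were higher by 2-fold or more, as were 8.13% of long noncoding and 5.16% of protein coding genes. No test was run between classes.

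The spike-ins' share of counts changed with STM2457 by a factor of 1.24 at 6 h (exact two-sided permutation p = 0.2), 1.22 in the knockdown (0.2), 1.04 in the emetine experiment (0.4) and 1.01 with emetine (0.8). With YTHDF2 siRNA the factor was 0.982 (exact two-sided permutation p = 0.7).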
